A study of Mus musculus with 18 samples.

How the data were processed

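RNA from the kidney cortex and medulla of male CD1 mice was measured on Illumina mouse bead arrays at P0, P2, P4, P6, P8, P10, P20, P30 and P90. Per the labels, RNA of 4 animals was pooled for each array, and each age and region has 1 array, 18 in all. The authors dissected the regions, isolated RNA with a QIAGEN RNeasy kit, checked it on a Bioanalyser, made biotin-labelled cRNA with an Ambion MessageAmp kit, and processed the arrays with lumi and limma in R.

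The deposited values are log2 intensities that the authors normalized between arrays; the series text does not state the background correction, the normalization method or whether the log2 scale is plain or variance-stabilised. The values run from 7.01 to 15.8. Differences between dim genes are compressed on either scale. A second deposited table holds scanner signals and detection p-values in 36 columns whose headers match no sample label. It was not used here, because columns cannot be assigned by order or by value. The plan to normalize the scanner signals and to filter on detection p-values was therefore replaced by the deposited normalized values and a filter on level.

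The table holds 46630 probes, of which 29975 carry 1 gene symbol and name 17711 genes. A probe was kept if it read above the array's 75th percentile on at least 3 arrays; these thresholds ran from 8.28 to 8.37. This kept 13920 probes. The brightest kept probe stood for each gene, which gave 8901 genes for testing; 2007 of these genes had more than 1 kept probe, and the other probes were compared for direction.

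Tests were run with limma 3.58.1 in R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment over the 8901 genes; a gene was called at an adjusted p under 0.05. Ages served as replicates. The region difference was the medulla coefficient in a model with age as a block (8 residual degrees of freedom). Age trends were slopes on log2(day + 1), scaled so that the coefficient is the fitted log2 change from P0 to P90, fitted for each region in 1 model (14 residual degrees of freedom). Fits on part of the ages kept this scale. Their slopes are therefore extended to the span from P0 to P90 and are not the change over the ages fitted. The difference in age trend was the interaction of region with that scale, with age as a block (7 residual degrees of freedom). A mid-age departure was the coefficient of a curve that is 0 at P0 and P90 and 1 at the middle of the scale, day 8.54, fitted beside the slope (12 residual degrees of freedom). Pairing of regions within an age was checked from the residuals, whose correlation between the regions ran from -0.03 at P2 to 0.779.

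The comparisons, the rule for naming genes, the alternatives and 37 lists of marker and pathway genes were fixed before the data were examined. The lists hold 437 members, 387 on the array and 287 measured, and 35 lists had the 3 measured members needed for a test; no adrenal or skeletal muscle gene was kept, so those lists were not tested. Each list was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 35 lists of a comparison. At the preset correlation 70 of 210 list tests were called, and 2 with an estimated correlation, the urothelium and the thin limb and inner medulla lists in the region difference. Members were counted with p-values adjusted over all genes and over the list alone.

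Genes were named by rule: for the region difference, the 10 with the largest difference each way among calls with the same sign at all 9 ages; for each age trend, the 10 with the largest fitted change each way among calls whose mean at P20, P30 and P90 lay on the same side of the mean at P0, P2 and P4; for the difference in age trend and the departures, the 5 largest each way; and for a list, up to 4 called members with the largest estimates, or the member with the smallest p where none was called.

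Alternatives for every comparison were every kept probe, the mean of a gene's probes, no filter, array weights and each age left out. Untransformed days and rank of age were run for the age trends and their difference, a natural spline with 3 degrees of freedom and each region alone for the age trends, and a fit without age as a block for the region difference and the difference in age trend. P0 to P10 alone was run for these and the age trends. P20 to P90 alone was run for the region difference, as was a model that added the interaction of region with the age scale to the age block. Lists were run with an estimated correlation, with each age left out and under the added alternatives. Added after the data were seen were the deposited values quantile normalized again, cyclic loess, a shift to a common array median, a filter at the 80th percentile on at least 9 arrays, and a fit without P4, P6 and P10. Splits of the samples were drawn 100 at a time, with the regions swapped within ages or the ages permuted; for the departures, residuals of the straight line were also permuted.

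The models were tested on simulated data with 200 changed genes among 8901. They recovered 94.0% of region differences of 0.5 log2, 85.1% and 82.1% of cortex and medulla trends of 1 log2, 74.6% of differences in trend of 1 log2, and 64.2% and 67.2% of departures of 0.5 log2 in cortex and medulla. Unchanged genes made up 4.08% to 7.49% of calls. The simulated noise was drawn independently for each gene and array. The real arrays have correlation between genes and between regions, so these percentages may not hold for the real calls. Correlations between markers were tested with 100000 permutations of the ages, both regions moved together. Probes without a gene symbol or with several were left out.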

Results

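Gene expression was measured in kidneys of male CD1 mice, an outbred stock, at 9 ages after birth: P0 (the day of birth), P2, P4, P6, P8, P10, P20, P30 and P90. At each age the kidney was divided into cortex, the outer zone with the glomeruli and most convoluted tubules, and medulla, the inner zone with loops of Henle, collecting ducts and papilla. Each region at each age gave 1 Illumina bead array hybridised with RNA pooled from 4 animals, so there were 18 arrays, 9 per region, and no array was repeated. In the mouse, nephrons continue to form for some days after birth, and the urine concentrating mechanism matures over the following weeks. The values are normalized log2 intensities. On each array 82.2% to 87.6% of the 8901 genes tested read above the level filter. Pearson's r between cortex and medulla of the same age, taken across genes, which are not independent replicates, ran from 0.950 to 0.980. The number of arrays limits the precision. With 1 array per age and region, the p-values of the fits measure the spread across ages around the fitted model. They measure neither the spread between animals nor that between repeated arrays of an age and region. Differences among dim genes are compressed by background, so small values near the filter are lower estimates of the change in RNA.

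Markers of neighbouring tissues were read on the same arrays. None of the 7 skeletal muscle genes on the array passed the level filter on any array, and 2 of 10 adrenal genes did, the highest at 8.34. The haemoglobin gene Hba-a1, a measure of blood, read between 13.85 and 15.25 and was highest at P20. The plasma protein genes Apoa2 and Ttr, abundant in liver, were highest on the P2 medulla array, at 9.97 and 9.85. Ucp1, the uncoupling protein of brown fat, read 11.89 on the P4 medulla array and 10.12 on the P4 cortex array, 10.67 on the P6 cortex array, and 11.57 and 10.87 on the P10 cortex and medulla arrays, and it was above the level filter on 15 of 18 arrays.

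The first comparison asked which genes differed between medulla and cortex over the whole postnatal period. The largest differences were in favour of medulla. Cryab, a small heat shock protein, was 11.2-fold higher in medulla than in cortex (log2 difference 3.49, SE 0.13, n = 9 ages, adjusted p = 1.04e-07), and Slc14a2, which encodes the urea transporters of the inner medulla, was 9.05-fold higher (3.18, SE 0.19, adjusted p = 1.43e-06). The water channel genes Aqp4 and Aqp2 and Fxyd4, a regulator of the sodium pump in the collecting duct, were higher in medulla by 2.42, 2.33 and 2.36 log2 units. Psca (2.68), the tight junction gene Cldn11 (2.28), the stress response gene Nupr1 (2.24), Nccrp1 (2.17) and Serpina6 (2.14), which encodes corticosteroid-binding globulin, completed the 10 largest differences in favour of medulla. Differences in favour of cortex were smaller. Hdc, which encodes the enzyme that makes histamine, was 1.98-fold higher in cortex (medulla minus cortex -0.99, SE 0.16, n = 9 ages, adjusted p = 0.00137), followed by Lhx1 (-0.93), a transcription factor of the early nephron, the calcium-binding protein gene Calb1 (-0.93), Pgam2 (-0.91), the podocyte and progenitor transcription factor gene Wt1 (-0.81), Hspa12a (-0.72), the carbonic anhydrase gene Car12 (-0.72), Osr2 (-0.72), Epb41l3 (-0.66) and Map7 (-0.63). These 20 genes were ranked among calls with the same sign at all 9 ages, so their agreement over ages comes from the rule. Slc14a2 read above the level filter on 4 of 9 cortex arrays, and other kept probes gave smaller differences for Slc14a2 (0.53) and Aqp4 (0.58).

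**Figure D1:**
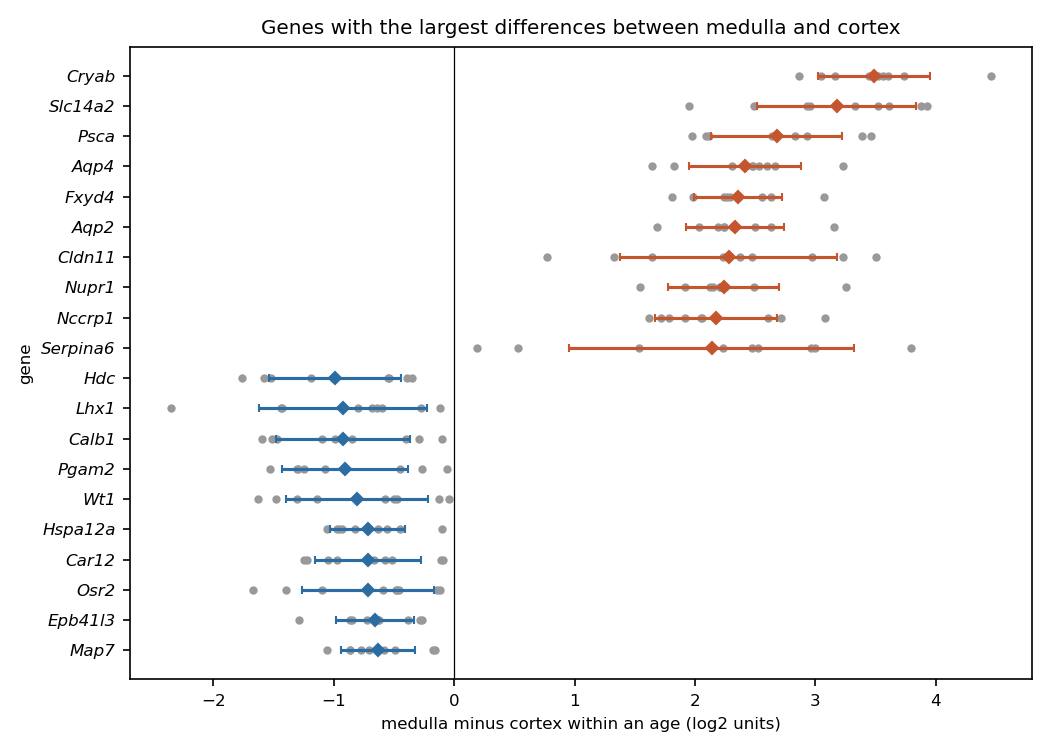
Medulla minus cortex in log2 units for the 20 genes with the largest differences each way among calls with the same sign at all 9 ages. Grey points are the 9 ages, diamonds their mean and bars the SD. Cryab lies farthest toward medulla at a mean of 3.49, and Hdc farthest toward cortex at -0.99.

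Lists of marker genes fixed in advance placed the nephron segments. All 7 urothelium genes measured were higher in medulla, 7 also when adjusted over the list alone, among them Upk2 (1.08), Upk3b (0.99) and Krt7 (0.93), with Upk2 above the level filter on 2 and Upk3b on 3 of 9 cortex arrays. The list moved toward medulla (median 0.93, camera adjusted p = 8.02e-08; adjusted p = 0.0200 with an estimated correlation). Of 5 genes of the thin limb and inner medulla, 4 were higher in medulla, and 4 when adjusted over the list alone, including the water channel gene Aqp1 (0.78) and Bst1, whose cortex readings were all at or below the level filter and which was at least 1.17-fold higher. The list lay on the medulla side (median 0.78, camera adjusted p = 1.01e-05; adjusted p = 0.0200 with an estimated correlation). Of 9 thick ascending limb genes, 8 were higher in medulla and 0 lower, 8 when adjusted over the list alone, among them Umod (1.61), the cotransporter gene Slc12a1 (0.99) and the chloride channel subunit gene Bsnd (0.68). For this list camera gave adjusted p = 2.89e-06, and adjusted p = 0.119 with an estimated correlation. Collecting duct principal cell genes were split, with 5 of 11 higher in medulla, led by Fxyd4, Aqp4, Aqp2 and the transcription factor gene Elf5 (1.85, above the level filter on 4 of 9 cortex arrays), and 2 lower. Adjusted over the list alone the principal cell counts were 5 and 3, the list median was 0.06 and its mean 0.77 (camera adjusted p = 0.0108; adjusted p = 0.243 with an estimated correlation). Osmoprotective genes, which serve cells in hypertonic surroundings, were higher in medulla for 5 of 8, and 5 when adjusted over the list alone. They included the betaine transporter gene Slc6a12, at least 2.98-fold higher over cortex readings at or below the filter, the tonicity-responsive transcription factor gene Nfat5 (1.37) and the kinase gene Sgk1 (0.71). Camera gave adjusted p = 1.01e-05, and adjusted p = 0.103 with an estimated correlation.

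Cortical segments showed the opposite side. All 6 podocyte genes measured were lower in medulla, and 6 when adjusted over the list alone, including Wt1, Synpo (-0.50) and Podxl (-0.47). The list median was -0.47 (camera adjusted p = 0.000540; adjusted p = 0.112 with an estimated correlation). Of 7 genes of the distal convoluted and connecting tubule, 3 were lower in medulla and 5 when adjusted over the list alone, with Calb1, the thiazide-sensitive cotransporter gene Slc12a3 (-0.80) and the sodium-calcium exchanger gene Slc8a1 (-0.60) as members. The list lay on the cortex side (median -0.60, camera adjusted p = 0.00717; adjusted p = 0.412 with an estimated correlation). Proximal tubule genes divided: 4 of 20 were lower in medulla, among them the lactate transporter gene Slc5a12 (-0.65) and the phosphate transporter gene Slc34a1 (-0.45), and the protease gene Napsa was higher (1.18). Adjusted over the list alone 5 were lower and 1 higher, and the list median was -0.40 (camera adjusted p = 0.0405; adjusted p = 0.793 with an estimated correlation). The intercalated cell list was not called (camera adjusted p = 0.225), although 3 of its 8 genes were lower in medulla, the anion exchanger gene Slc26a4 (-0.65) and the ammonia transporter gene Rhbg (-0.51) among them, and Aqp6 was higher (0.48). The calls of Slc5a12 and Slc34a1 were not stable: Slc5a12 lost its call without P6, P8, P10, P20, P30 or P90, with values from -0.65 to -0.54, and Slc34a1 without P4, P6, P8, P10 or P20, with values from -0.45 to -0.36. The proximal tubule list lost its call without P6, P8, P10, P20, P30 or P90 (camera adjusted p from 0.0604 to 0.138).

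Stromal, vascular and signalling genes were mostly higher in medulla. Of 15 extracellular matrix genes, 9 were higher and 0 lower, 12 when adjusted over the list alone, including Col3a1 (0.94) and the fibronectin gene Fn1 (0.73). The list's camera test gave adjusted p = 1.01e-05, and adjusted p = 0.164 with an estimated correlation. Of 11 basement membrane genes, 7 were higher, 8 when adjusted over the list alone, including Col4a4 (0.78) and the perlecan gene Hspg2 (0.36) (camera adjusted p = 0.000130; adjusted p = 0.112 with an estimated correlation). Of 11 endothelial genes 6 were higher, 8 over the list alone, with Esam (0.80) and Plvap (0.67), a protein of fenestrated capillaries (camera adjusted p = 0.000130; adjusted p = 0.103 with an estimated correlation). Of 5 smooth muscle genes 4 were higher, 5 over the list alone, with the smooth muscle actin gene Acta2 (0.70) (camera adjusted p = 0.00373; adjusted p = 0.245 with an estimated correlation). Developing stroma genes were higher for 4 of 7, 4 over the list alone, with the signalling ligand gene Wnt5a (1.31, and 0.44 on another probe) and Smoc2 (1.20) (camera adjusted p = 0.00204; adjusted p = 0.188 with an estimated correlation). The Wnt pathway list had 5 of 8 genes higher and 1 lower, 6 and 1 over the list alone, with Apcdd1 (1.58) and Wnt9b (1.18), each above the level filter on 1 of 9 cortex arrays, and Wnt7b, at least 1.34-fold higher (camera adjusted p = 0.00147; adjusted p = 0.235 with an estimated correlation). The Hedgehog list had 3 of 6 higher, 4 over the list alone, with Ihh (0.37) and Shh, at least 1.09-fold higher over all 9 ages (camera adjusted p = 0.00717; adjusted p = 0.112 with an estimated correlation). The Shh call ended over P20 to P90 alone (0.0265) and without P4, P6 and P10 (0.31).

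Glycolysis genes were higher in medulla for 5 of 9, and 5 when adjusted over the list alone. They included the pyruvate kinase gene Pkm (0.71) and the phosphofructokinase gene Pfkl (0.70). Camera gave adjusted p = 0.000998, and adjusted p = 0.0636 with an estimated correlation. Cell cycle genes were lower in medulla for 10 of 17 and higher for 0, 13 lower when adjusted over the list alone, among them Mcm5 (-0.36) and Aurka (-0.31). The whole list lay on the cortex side (camera adjusted p = 1.83e-05; adjusted p = 0.365 with an estimated correlation). Ureteric tip genes were lower in medulla for 2 of 4, and 2 over the list alone, these being Etv5 (-0.27) and Sox9 (-0.43), both transcription factor genes of the branching tip (camera adjusted p = 0.0428; adjusted p = 0.441 with an estimated correlation). Sox9 was above the level filter on 2 of 9 medulla arrays and lost its call without P0, P2, P4, P6, P8, P10 or P30, with values from -0.46 to -0.34. The remaining 17 lists were not called (camera adjusted p from 0.121 to 0.974). Among these, hypoxia response genes were higher for 3 of 9 and lower for 1. Androgen-responsive genes were higher for 1 of 11, Kap (1.34), and lower for 1, with a median of -0.06 and a mean of 0.14. Committing nephron genes were higher for 3 of 7, with Wnt4 (0.76, above the level filter on 2 of 9 cortex arrays), and lower for 1, with a median of -0.12 against a test direction toward medulla. The macrophage, nephron progenitor and fetal growth lists, also not called, had a median opposed to the test. The ureteric tip list lost its call without P0, P2 or P4 (camera adjusted p = 0.0951, 0.0969 and 0.0584), and the Wnt pathway list under a stricter filter (0.742).

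In total 2155 of 8901 genes differed between the regions in limma's blocked model with age as the block (adjusted p under 0.05), 1117 higher in medulla and 1038 higher in cortex, and 3460 passed at unadjusted p under 0.05. All 73 differences of 2-fold or more were higher in medulla. Of all 8901 genes, 986 had the same sign at all 9 ages; chance gives this to 0.391% of genes. Without age as a block 690 genes were called, and among the genes named above those not called were Hdc, Lhx1, Wt1, Osr2, Synpo, Podxl, Slc5a12, Slc34a1, Slc26a4, Bsnd, Acta2, Col3a1, Fn1, Col4a4, Hspg2, Ihh, Pkm, Kap, Mcm5, Aurka and Sox9. Without P4, P6 and P10, the ages with the highest Ucp1 readings, 424 were called, and P20 to P90 alone gave 1002. Over P20 to P90 alone the difference of Apcdd1 was -0.0262 and that of Sox9 0.000782. Neither kept its sign or its call (adjusted p = 0.891 and 0.996 in limma). Calls also ended over these ages for Serpina6 (adjusted p = 0.157), Smoc2 (0.58), Kap (0.47), Acta2 (0.19), Col3a1 (0.12), Col4a4 (0.10) and Shh (0.0265), and for Slc34a1 (-0.39), Lhx1 (-0.34), Mcm5 (-0.28), Osr2 (-0.25), Aurka (-0.25), Wt1 (-0.21) and Podxl (-0.11). Over P0 to P10 alone they ended for Slc12a3 (-0.76), Slc34a1 (-0.48), Slc26a4 (-0.47) and Slc5a12 (-0.41). Car12, Slc8a1, Rhbg and Wnt4 each lost the call in an alternative (highest adjusted p in limma 0.0637, 0.0749, 0.0749 and 0.0551).

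The second comparison asked how expression changed with age in the cortex, with a straight line over log2 of age from P0 to P90. The cytochrome pseudogene Cyp4b1-ps2 rose by a fitted 7.84 log2 units (SE 1.72, n = 9 ages, adjusted p = 0.00131), the secreted nuclease gene Dnase1 by 7.80 (SE 1.44, adjusted p = 0.000363) and Kap, the kidney androgen-regulated protein, by 6.40 (SE 0.56, adjusted p = 5.40e-06). Igf2, the fetal growth factor, fell by a fitted 7.72 (SE 0.95, n = 9 ages, adjusted p = 2.37e-05). Its readings were 14.46 at P0 and 8.49 at P90, a smaller change than the fitted line gives. The imprinted gene Mest fell by a fitted 5.06 (SE 0.44, adjusted p = 5.40e-06). Among the others, Cyp2e1 (7.10), the carboxylesterase gene Ces1d (6.98), the glycosyltransferase gene Ugt3a2 (6.50), the fatty acid hydroxylase gene Cyp4a12a (6.19), the methyltransferase gene Inmt (6.18), Eri2 (5.67) and the growth factor gene Egf (5.35) completed the 10 that rose most. For 1 of these genes, Eri2, 1 of the 2 other probes went the opposite way, and another kept probe gave 0.30 for Egf and -0.77 for Fstl1. Cyp4a12a was above the level filter on 2 and Eri2 on 4 of 9 cortex arrays, so their fitted rises start from background and their sizes are uncertain. The replication-dependent histone genes H2ac12 (-5.82), H2ac6 (-5.69), H2ac13 (-5.48), H2ac23 (-5.47) and H2ac15 (-5.45), with Fstl1 (-5.24), the growth factor gene Ptn (-4.93) and the glypican gene Gpc3 (-4.87), completed the 10 that fell most. These histone genes, and Cyp4b1-ps2 and its parent gene, are close in sequence, so probes may not tell them apart.

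Proximal tubule genes rose in the cortex for 18 of 20 and fell for 0, 18 also when adjusted over the list alone, among them the urate transporter gene Slc22a12 (4.09), the glucose transporter gene Slc5a2 (3.46) and the amino acid transporter gene Slc6a19 (2.98, and 1.38 on another probe). The list median was 2.11 (camera adjusted p = 1.52e-06; adjusted p = 0.681 with an estimated correlation). Androgen-responsive genes rose for 10 of 11, and 10 over the list alone, with a median of 3.07 (camera adjusted p = 0.00306; adjusted p = 0.681 with an estimated correlation). Organic ion and drug transport genes rose for 5 of 8, 6 over the list alone, with Slc22a2 (2.67) and Slc47a1 (2.40) (camera adjusted p = 0.0343; adjusted p = 0.681 with an estimated correlation). Oxidative phosphorylation genes rose for 8 of 11, and 8 over the list alone, by less, with the complex subunit genes Sdhb (1.14) and Cox6a1 (0.86) as examples (median 0.58, camera adjusted p = 0.0136; adjusted p = 0.681 with an estimated correlation). Cell cycle genes fell for 16 of 17, and 16 over the list alone, including the replication gene Mcm4 (-3.14) and the topoisomerase gene Top2a (-2.82) (median -1.90, camera adjusted p = 1.10e-05; adjusted p = 0.681 with an estimated correlation). Fetal growth and imprinted genes fell for 9 of 10, and 9 over the list alone, with Igf2, Mest, the cell cycle inhibitor gene Cdkn1c (-4.12) and Ndn (-4.02) (median -2.93, camera adjusted p = 0.000200; adjusted p = 0.681 with an estimated correlation). Extracellular matrix genes fell for 9 of 15, and 9 over the list alone, including the crosslinking enzyme gene Lox (-2.83) and Col1a1 (-2.54) (median -1.03, camera adjusted p = 0.0343; adjusted p = 0.681 with an estimated correlation). The extracellular matrix list lost its call without P90 (camera adjusted p = 0.107) and the oxidative phosphorylation list without P0 (0.0611). The androgen-responsive, organic ion and drug transport and extracellular matrix lists lost it under a stricter filter (0.0819 for each).

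Several lists had called members although the list test did not pass in the cortex. Umod, of the thick ascending limb, rose by 2.85, and 4 of the 9 genes of that list rose (camera adjusted p = 0.361). The kallikrein gene Klk1, of the connecting tubule, rose by 3.57, and 3 of 7 genes of its list rose (camera adjusted p = 0.140). Wt1 (-4.32) and Podxl (-1.80) were among the 4 of 6 podocyte genes that fell, and 1 rose (camera adjusted p = 0.200). All 4 ureteric tip genes fell, Sox9 by 1.69 (camera adjusted p = 0.0575). Of 7 nephron progenitor genes 4 fell, 5 over the list alone, with Uncx (-2.66) and the tip-inducing factor gene Gdnf (-1.80) among them, above the level filter on 3 and 2 of 9 cortex arrays, so that both falls end at background, and 1 that rose (camera adjusted p = 0.144). Of 4 lymphocyte and MHC class II genes, 3 rose, with Cd74 (2.48, and 0.68 on another probe), and 1 fell (camera adjusted p = 0.200). Fatty acid oxidation genes rose for 7 of 9, and 7 over the list alone (camera adjusted p = 0.0552). The lists whose median or mean opposed the test were Wnt pathway (median -0.21, test upward), glycolysis (median 0.34, mean -0.20) and osmoprotective (median -0.07, test upward).

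In the cortex 4945 of 8901 genes changed with age (limma, adjusted p under 0.05), 2283 upward and 2662 downward, 1751 of them by 2-fold or more, and 5411 passed at unadjusted p under 0.05. P0 to P10 alone gave 2952 calls. Here and below, trend values from P0 to P10 or without P90 are slopes extended to the span from P0 to P90. They are larger than the fitted change over the ages used. Over P0 to P10 Inmt had a falling slope (-1.01, adjusted p = 0.0329 in limma). The slope of Cyp4a12a changed sign but was not called (-0.18, adjusted p = 0.637 in limma). Calls also ended over P0 to P10 for Slc22a2 (1.08), Slc22a12 (0.85), Eri2 (0.36), Cyp2e1 (0.34), Cyp4b1-ps2 (0.22), Podxl (-0.0504), Col1a1 (-0.41) and Cdkn1c (-1.36). Leaving out P90 gave 4195 calls and ended those of Cyp4a12a (3.84), Inmt (3.81), Eri2 (4.33) and Col1a1 (-2.13). Leaving out P0 ended that of Cox6a1 (0.81), which was the same in 20 of 23 alternatives. Slc5a2, Gdnf, Uncx, Umod, Klk1, Sox9 and Sdhb each lost the call in an alternative. Their highest adjusted p in limma was 0.198, 0.186, 0.147, 0.120, 0.0935, 0.0757 and 0.0613.

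The third comparison asked the same of the medulla. Many of the genes with the largest changes were those of the cortex. Cyp4b1-ps2 rose by a fitted 7.32 log2 units (SE 1.72, n = 9 ages, adjusted p = 0.00425), Cyp4a12a by 6.09 (SE 1.86, adjusted p = 0.0165) and Egf by 5.68 (SE 0.90, adjusted p = 0.000599). Igf2 fell by a fitted 7.09 (SE 0.95, adjusted p = 0.000231). Its readings were 14.27 at P0 and 8.46 at P90, again a smaller change than the fitted line gives. Dnase1 (6.54), Inmt (6.08), Ces1d (6.07), Cyp2e1 (6.02), Eri2 (5.93), the steroid hydroxylase gene Cyp2a4 (5.18) and Mpv17l (4.78) also rose. Cdkn1c (-5.37), Nrep (-4.96), H2ac6 (-4.74), H2ac13 (-4.73), Basp1 (-4.57), Fstl1 (-4.57), H2ac23 (-4.53), Mest (-4.46) and the defensin gene Defb19 (-4.27) fell. Another kept probe gave 0.37 for Egf and -0.81 for Fstl1, and 1 of the 2 other probes of Eri2 went the opposite way. Cyp4a12a was above the level filter on 2, Eri2 on 3 and Cyp2a4 on 3 of 9 medulla arrays. Their fitted rises therefore start from background and their sizes are uncertain.

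Extracellular matrix genes fell in the medulla for 11 of 15, 13 when adjusted over the list alone, including Col1a1 (-3.87) and Lox (-3.17) (median -2.25, camera adjusted p = 8.80e-05; adjusted p = 0.585 with an estimated correlation). Basement membrane genes fell for 8 of 11, and 8 over the list alone, with Col4a1 (-3.03) and the laminin gene Lamc1 (-2.36) (camera adjusted p = 0.00827; adjusted p = 0.619 with an estimated correlation). Smooth muscle genes fell for 4 of 5, and 4 over the list alone, with Acta2 (-4.25, and -2.96 and -1.48 on other probes) and the myosin gene Myh11 (-1.28) (camera adjusted p = 0.0135; adjusted p = 0.585 with an estimated correlation). Developing stroma genes fell for 5 of 7, 6 over the list alone, and 1 rose. Penk (-2.34) and Wnt5a (-1.55, and -0.15 on another probe) were among those that fell (camera adjusted p = 0.0420; adjusted p = 0.585 with an estimated correlation). Cell cycle genes fell for 13 of 17, 15 over the list alone where 1 rose, with Mcm4 (-2.06) and Top2a (-1.75) (camera adjusted p = 8.80e-05; adjusted p = 0.585 with an estimated correlation). Fetal growth genes fell for 9 of 10, and 9 over the list alone, with Ndn (-3.24) beside Igf2, Cdkn1c and Mest (median -2.57, camera adjusted p = 6.70e-06; adjusted p = 0.329 with an estimated correlation). Podocyte genes fell for 5 of 6, and 5 over the list alone, with Wt1 (-2.63) and Podxl (-1.49) (camera adjusted p = 0.0440; adjusted p = 0.585 with an estimated correlation). Outside the called lists, the Wnt pathway gene Apcdd1 fell by 3.36 and 3 of 8 genes of its list fell while 1 rose, without a list call. Nfat5 (-2.12) was the 1 of 8 osmoprotective genes that fell (camera adjusted p = 0.952). The basement membrane list lost its call without P90 (camera adjusted p = 0.129). The developing stroma list lost it without P20, P30 or P90 (0.0503, 0.0545 and 0.0687) and the podocyte list without P0, P2 or P20 (0.0852, 0.0697 and 0.0503). Under a stricter filter the developing stroma (0.207) and smooth muscle (0.108) lists lost it.

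Proximal tubule genes rose in the medulla for 10 of 20, 11 over the list alone, and 1 fell. Slc22a12 (3.86) and the fatty acid transport gene Slc27a2 (2.50) were among those that rose (median 1.29, camera adjusted p = 0.000553; adjusted p = 0.585 with an estimated correlation). Androgen-responsive genes rose for 9 of 11, 11 over the list alone, with Cyp4a12a, Cyp2e1 and Kap (3.79) (median 3.65, camera adjusted p = 0.000216; adjusted p = 0.585 with an estimated correlation). Organic ion and drug transport genes rose for 3 of 8, and 3 over the list alone, with Slc22a7 (1.58) and Slc47a1 (1.46) (camera adjusted p = 0.0385; adjusted p = 0.585 with an estimated correlation). Oxidative phosphorylation genes rose for 2 of 11, 1 over the list alone, these being Ndufv1 (0.95) and Cox5a (0.56) (camera adjusted p = 0.0341; adjusted p = 0.667 with an estimated correlation). Of 4 lymphocyte and MHC class II genes 3 rose, and 3 over the list alone, with Cd74 (2.36, and 0.52 on another probe) and H2-Ab1 (0.92), which serve antigen presentation (camera adjusted p = 0.0385; adjusted p = 0.585 with an estimated correlation). Umod rose by 2.30, and 2 of 9 thick ascending limb genes rose (camera adjusted p = 0.0679). Nephron progenitor and ureteric tip genes had 0 of 7 and 0 of 4 called in limma (camera adjusted p = 0.641 and 0.755). The principal cell and glycolysis lists, not called, had medians and means of opposite sign. The organic ion and drug transport list lost its call without P90 (camera adjusted p = 0.0898) and under a stricter filter (0.108). The oxidative phosphorylation list lost it without P30 or P90 (0.0600 and 0.0747) and the lymphocyte and MHC class II list without P20 or P90 (0.0503 and 0.0622).

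In the medulla 3514 genes changed with age (limma), 1508 upward and 2006 downward, 1119 of them by 2-fold or more, and 4387 passed at unadjusted p under 0.05. P90 weighed on this count, which was 1337 without it. Without P90 the calls ended for Cyp4b1-ps2 (6.23), Cyp2e1 (4.75), Eri2 (4.43), Inmt (3.88), Cyp4a12a (3.81), Slc22a12 (3.60), Cyp2a4 (3.40), Slc22a7 (1.52), Slc47a1 (0.77), Ndufv1 (0.76) and H2-Ab1 (0.56), which had risen. They also ended for Wnt5a (-1.12), Nfat5 (-1.33), Podxl (-1.42), Col4a1 (-2.02), Ndn (-2.64), Nrep (-3.37), Fstl1 (-3.64) and Cdkn1c (-4.41), which had fallen. Slc47a1 also lost its call without P30 (1.22), and Cox5a without P2, P4, P6, P20, P30 or P90 (0.46 to 0.70). The Cox5a result was the same in only 11 of 23 alternatives. P0 to P10 alone gave 353 calls, and over these ages 17 of the genes named above had an estimate of the opposite sign. None of the 17 was called there (adjusted p in limma from 0.0595 for Nrep to 0.993 for Eri2), so a reversal was not shown. Estimates above 0 were those of Nfat5 (1.02), Cdkn1c (0.97), Nrep (0.91), Apcdd1 (0.49), Fstl1 (0.36), Wnt5a (0.36), Ndn (0.0914) and Col4a1 (0.0576). Estimates below 0 were those of Cyp2e1 (-1.45), Slc47a1 (-0.87), Inmt (-0.84), Slc22a12 (-0.23), Ndufv1 (-0.15), Cox5a (-0.0717), Cyp4a12a (-0.0556), Cyp4b1-ps2 (-0.0545) and Eri2 (-0.00570). Calls also ended over P0 to P10 for Egf (3.25), Ces1d (2.81), Umod (2.02), Cd74 (0.62), Dnase1 (0.41), H2-Ab1 (0.18), Cyp2a4 (0.12), Slc22a7 (0.11), Mpv17l (0.0944) and Slc27a2 (0.0934). They ended as well for Wt1 (-2.94), Lox (-1.51), Podxl (-1.47), H2ac13 (-1.38), H2ac23 (-1.02), H2ac6 (-0.89), Top2a (-0.69), Lamc1 (-0.54), Acta2 (-0.41), Mcm4 (-0.35), Basp1 (-0.24), Col1a1 (-0.24) and Penk (-0.17).

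The age trends of both regions overlapped: 1271 genes rose in both, 1649 fell in both, and 4 went opposite ways. Of 2021 genes called in cortex only, 1823 had the same sign in medulla. The courses differed in timing from gene to gene. Igf2 declined from P0 onward, whereas Cdkn1c in the medulla was still at 14.26 at P10 and read 11.42 at P20. Kap read 9.13 in the cortex and 10.96 in the medulla at P0, and 14.52 and 14.57 at P90.

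**Figure D2:**
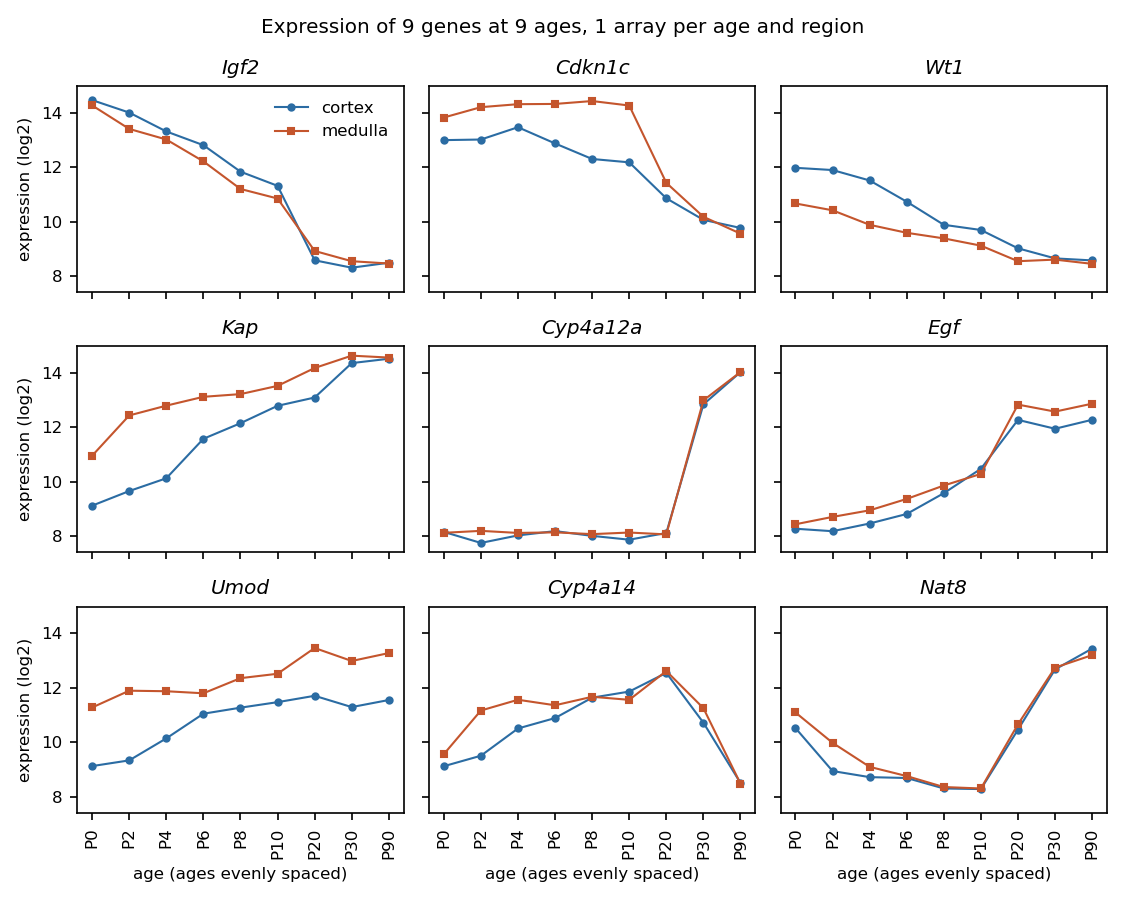
Expression in log2 units of 9 genes at the 9 ages, evenly spaced, with 1 line per region and 1 array per point. Igf2 and Wt1 decline from birth, Egf climbs through P20, and Cyp4a12a stays near 8.13 in cortex until P20 and reads 12.85 at P30.

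A group of genes stepped up between P20 and P30 in both regions. Inmt went from 8.88 in cortex and 9.41 in medulla to 13.57 and 13.43. Cyp4a12a, Cyp2d9 and Cyp7b1, an oxysterol hydroxylase gene, were below the level filter in both regions at P20, so their steps are lower bounds. At P30 Cyp4a12a read 12.85 and Cyp7b1 9.10 in cortex, and Cyp2d9 8.80 and 10.67 in cortex and medulla. At P90 Cyp4a12a read 14.04 and Cyp7b1 12.84 in medulla. These P90 readings include any change after P30 and are not to be set against the P30 cortex readings. The median step of the 11 androgen-responsive genes from P20 to P30 was 1.27 in cortex and 2.49 in medulla, against 0.71 and 0.54 for the next largest step, from P30 to P90. In each region 8 of the 11 genes read more than 1 log2 unit higher at P30 than at P20, as against 0.876% of all genes tested in cortex and 1.57% in medulla with a step of at least that size. This step was chosen for description after its values were seen, and each age has 1 array per region.

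**Figure D3:**
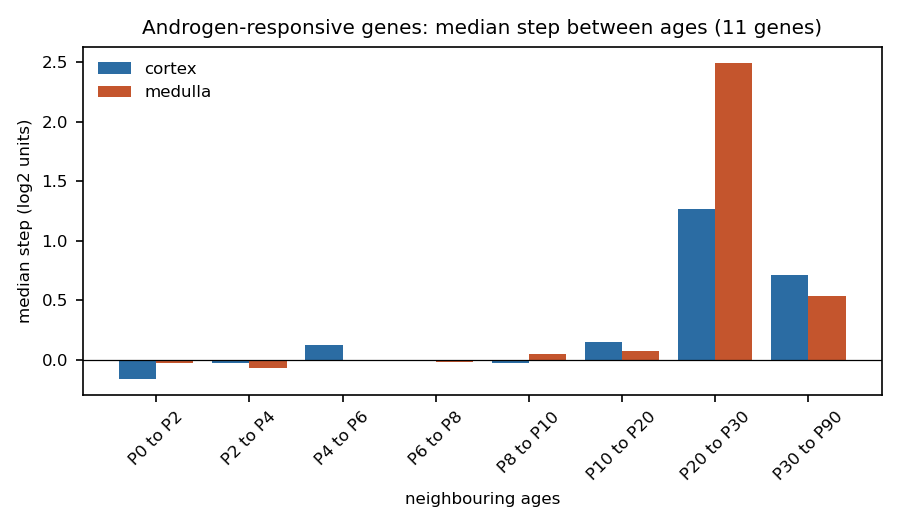
Median step in log2 units of the 11 androgen-responsive genes between neighbouring ages, 1 bar per step and region. The bars from P20 to P30, at 1.27 in cortex and 2.49 in medulla, are the highest.

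The fourth comparison asked whether genes changed with age differently in the medulla than in the cortex. Reln, an extracellular signalling glycoprotein, read 10.22 at P0 and 8.27 at P90 in the cortex and 9.39 and 8.96 in the medulla. Its medulla slope exceeded its cortex slope by 1.67 log2 units (SE 0.18, n = 9 ages, adjusted p = 0.0133). Nts, which encodes the peptide neurotensin, read 10.65 in the newborn medulla and 8.12 at P90. It stayed at or below 8.33 in the cortex, above the level filter on 1 of 9 arrays, so its difference in slope (-3.12, SE 0.45, adjusted p = 0.0261) is set against readings near background. The heparan sulfate modifying gene Hs6st2 (1.58), the glutathione transferase gene Gstm2 (1.57), Sox9 (1.45) and Hoxb6 (1.38) also had higher slopes in medulla. Ranbp3l (-1.92), the receptor ligand gene Gas6 (-1.80), the glutathione transferase gene Gsta3 (-1.79) and the peroxisomal oxidase gene Hao2 (-1.75) had lower slopes. The nephron progenitor gene Sall1 was among the called genes (0.94, adjusted p = 0.0261).

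The gaps between the regions moved in opposite directions for different lists. Proximal tubule genes were higher in medulla at P0 and P2 (median gap 0.39 and 0.55), near 0 at P4 (0.03) and higher in cortex from P6 (-0.63) through P10 (-0.88) to P90 (-0.42). Slc6a19 had the smallest p of that list (-1.66, adjusted p = 0.0937, and -0.82 on another probe), 0 of 20 genes were called and 2 adjusted over the list alone (list median -1.01, camera adjusted p = 2.30e-05; adjusted p = 0.608 with an estimated correlation). Ureteric tip genes were lower in medulla at P0 (-1.07) and level at P90 (0.05), and 1 of 4, Sox9, was called and 3 over the list alone (median 1.32, camera adjusted p = 0.000922; adjusted p = 0.608 with an estimated correlation). Smooth muscle genes were higher in medulla at P0 (0.87) and level at P90 (0.00), with Acta2 at -1.46 (adjusted p = 0.0663), 0 of 5 called and 4 over the list alone (camera adjusted p = 0.00272; adjusted p = 0.608 with an estimated correlation). Extracellular matrix genes went from 0.59 to -0.01, with 0 of 15 called and 6 over the list alone (camera adjusted p = 0.000922; adjusted p = 0.608 with an estimated correlation). Their lowest p was that of Dcn (-1.96, adjusted p = 0.0615), for which 1 of 3 other probes went the opposite way. Cell cycle genes went from -0.57 to -0.08, with Mcm4 at 1.07 (adjusted p = 0.0668), 0 of 17 called and 1 over the list alone (camera adjusted p = 0.000265; adjusted p = 0.608 with an estimated correlation). Committing nephron genes had 0 of 7 called and 2 over the list alone, Lhx1 at 1.88 (adjusted p = 0.0815, and 0.84 on another probe) among the 7 (median 0.50, camera adjusted p = 0.0294; adjusted p = 0.608 with an estimated correlation). Wnt pathway genes, whose gap was 0.49 at P0, 0.85 at P8, widest at P10 and 0.16 at P90, had 0 of 8 called and 2 over the list alone, with Sfrp1 at -0.98 (adjusted p = 0.0663) (camera adjusted p = 0.0489; adjusted p = 0.608 with an estimated correlation). The nephron progenitor list was not called (camera adjusted p = 0.0520), with 1 of 7 genes, Sall1, called and 3 over the list alone. Median, mean and test differed in sign for the lymphocyte, glycolysis and prostaglandin lists, none of them called. The Wnt pathway list lost its call without P4, P20, P30 or P90 (camera adjusted p from 0.0515 to 0.315), and under a stricter filter it (0.105), the committing nephron (0.0713) and the smooth muscle list (0.0605) lost theirs.

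**Figure D4:**
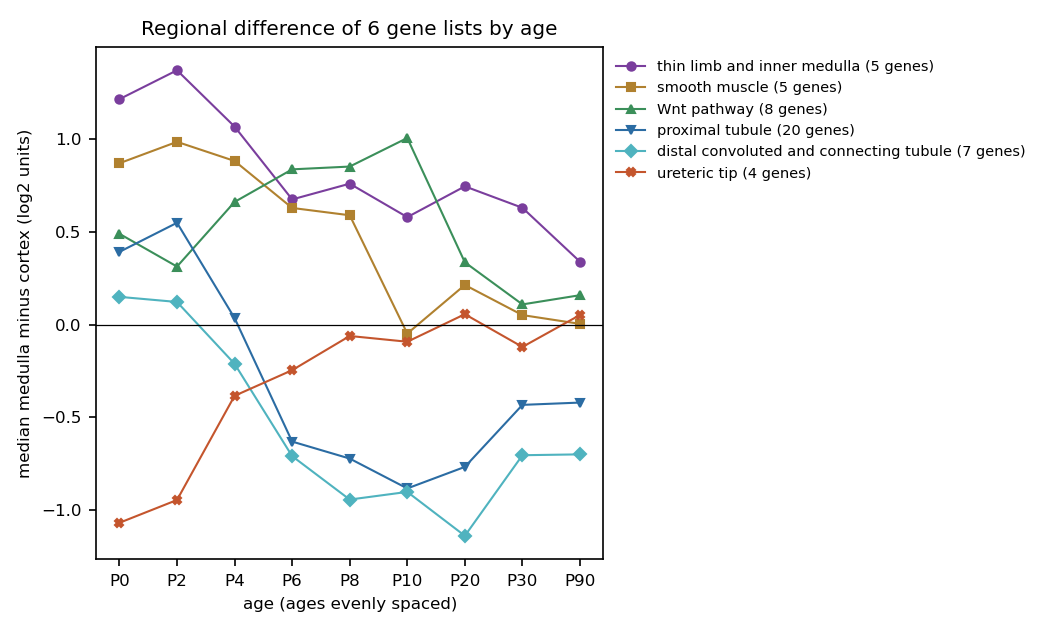
Median of medulla minus cortex in log2 units for 6 gene lists at each of the 9 ages, 1 line per list. The proximal tubule line crosses 0 after P4, and the ureteric tip line starts at -1.07.

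Of 8901 genes 36 differed in age trend (limma), 16 with a higher and 20 with a lower slope in medulla, and 1750 passed at unadjusted p under 0.05. The count depended on the ages: it was 0 without P2 or without P30 (1257 and 1492 genes at unadjusted p under 0.05), so every gene call above ended there; that of Hoxb6 also ended under a stricter filter (adjusted p = 0.0540). It was 22, 10, 17, 22 and 169 without P0, P4, P6, P8 and P90. Over P0 to P10 alone it was 1511, where Gas6 (-1.45), Gsta3 (-1.54) and Ranbp3l (-0.92), again as slopes extended to P90, were not called. It was 395 on the rank of age, 1 on untransformed days and 6 without age as a block, and without P4, P6 and P10 it was 0 (1439 unadjusted).

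The last comparisons asked which genes departed from the straight line at mid ages, with the middle of the age scale near day 8.54. In both regions the fatty acid hydroxylase gene Cyp4a14 rose and then fell: it read 9.12 in cortex and 9.56 in medulla at P0, 12.55 and 12.61 at P20, and 8.50 and 8.48 at P90, with departures of 2.71 (SE 0.57, n = 9 ages, adjusted p = 0.0323) and 2.77 (SE 0.57, adjusted p = 0.0151). Nat8, an acetyltransferase gene, did the reverse, from 10.52 and 11.09 at P0 through 8.28 and 8.30 at P10 to 13.44 and 13.20 at P90 (-3.23, SE 0.76, adjusted p = 0.0450 in cortex and -3.26, SE 0.76, adjusted p = 0.0235 in medulla). In medulla the iron-siderophore binding gene Lcn2 (2.08) read 8.55 at P0, 11.53 at P10 and 8.87 at P90, and Igfbp2 (1.80), a binding protein of insulin-like growth factors, 8.93, 10.99 and 8.57. Cdkn1c (2.19) and Nrep (2.37) also lay above the line. Inmt (-3.05), Cyp2j13 (-2.46), Cyp7b1 (-2.40) and Cyp2a4 (-2.27) lay below it. In cortex Nrep (2.19), the channel subunit gene Kcne1l (1.54), the aminopeptidase gene Xpnpep2 (1.48) and the parvalbumin gene Pvalb (1.46) lay above the line, and Cyp2a4 (-1.99), Cyp2d9 (-1.70), Ldhd (-1.34) and the haem oxygenase gene Hmox1 (-1.27) below. Cyp2a4 was above the level filter on 3 and Cyp2d9 on 2 of 9 arrays in each region, so their departures are set by readings at background up to P10 or P20.

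In cortex 13 lists departed, each call being lost with an estimated correlation. Distal convoluted and connecting tubule genes lay above the line for 2 of 7, with Slc12a3 (1.05), and 6 adjusted over the list alone (camera adjusted p = 7.16e-05; adjusted p = 0.270 with an estimated correlation). So did 1 of 9 thick ascending limb genes, Bsnd (adjusted p = 0.0306), and 6 over the list alone (camera adjusted p = 0.000578; adjusted p = 0.284 with an estimated correlation). Of the intercalated cell genes 2 of 8 lay above it, with the ammonia transporter gene Rhcg (0.62), and 5 over the list alone (camera adjusted p = 5.62e-05; adjusted p = 0.270 with an estimated correlation). Basement membrane genes lay above it for 3 of 11, with Col4a1 (1.27), and 6 over the list alone (camera adjusted p = 5.69e-06; adjusted p = 0.270 with an estimated correlation). Cell cycle genes did so for 1 of 17, Mcm5 (0.82), and 7 over the list alone (camera adjusted p = 8.83e-06; adjusted p = 0.452 with an estimated correlation). Podocyte, endothelial, principal cell, extracellular matrix and oxidative phosphorylation genes were shifted above it with 0 genes called in limma and 4, 6, 3, 2 and 0 over the list alone (camera adjusted p = 0.00834, 0.00109, 0.0450, 0.00721 and 0.00834; adjusted p = 0.270, 0.452, 0.512, 0.527 and 0.537 with an estimated correlation). Ureteric tip genes lay below the line for 2 of 4, with the receptor gene Gfra1 (-0.71), and 4 over the list alone (camera adjusted p = 0.000182; adjusted p = 0.270 with an estimated correlation). Nephron progenitor genes did so for 1 of 7, Gdnf (-0.89, SE 0.08, adjusted p = 3.13e-05), which was below the level filter from P4 on, so that its bend is set by background, and 4 over the list alone (camera adjusted p = 0.00834; adjusted p = 0.270 with an estimated correlation). Androgen-responsive genes lay below it for 2 of 11, Cyp2d9 among them, and 9 over the list alone (median -1.28, camera adjusted p = 1.08e-06; adjusted p = 0.270 with an estimated correlation). Single ages ended list calls: without P0 those of the cell cycle, extracellular matrix and podocyte lists (camera adjusted p = 0.610, 0.259 and 0.903). Without P90 those of the distal convoluted and connecting tubule, oxidative phosphorylation, thick ascending limb and ureteric tip lists ended (0.429, 0.882, 0.109 and 0.320). Without either the nephron progenitor call ended (0.251 and 0.112), and without P0, P10 or P90 that of the collecting duct principal cell list (0.267, 0.134 and 0.0586). The nephron progenitor call also ended under a stricter filter (0.501). Test and median or mean differed in sign for the hepatocyte, developing stroma, Wnt pathway and glycolysis lists, none of which was called.

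In medulla 13 lists departed, again each lost with an estimated correlation. Basement membrane genes lay above the line for 6 of 11, with Nid1 (1.31) and Col4a1 (1.30), and 8 over the list alone (camera adjusted p = 6.12e-07; adjusted p = 0.494 with an estimated correlation). Extracellular matrix genes did so for 4 of 15, with Col3a1 (1.21), and 9 over the list alone (camera adjusted p = 0.000877; adjusted p = 0.494 with an estimated correlation). Cell cycle genes lay above it for 5 of 17, with Mcm5 (1.03) and Birc5 (0.89), and 11 over the list alone (camera adjusted p = 6.12e-07; adjusted p = 0.494 with an estimated correlation). Endothelial genes did so for 4 of 11, with Plvap (1.07), and 8 over the list alone (camera adjusted p = 0.000411; adjusted p = 0.494 with an estimated correlation). Thin limb and inner medulla genes lay above it for 3 of 5, with Slc14a2 (1.55, SE 0.22, adjusted p = 0.00452, and 0.0815 on another probe) and Cryab (adjusted p = 0.0274), and 3 over the list alone (camera adjusted p = 0.0278; adjusted p = 0.494 with an estimated correlation). Wnt pathway genes did so for 3 of 8, with Wnt9b (0.87, SE 0.12, adjusted p = 0.00452) and Wnt7b (0.47), and 6 over the list alone, where 2 lay below (camera adjusted p = 0.0153; adjusted p = 0.494 with an estimated correlation). Principal cell genes for 1 of 11 and developing stroma genes for 2 of 7 lay above it, 3 and 4 over the list alone, where 1 stroma gene lay below (camera adjusted p = 0.0310 and 0.0451; adjusted p = 0.494 with an estimated correlation for each). Below the line lay 1 of 20 proximal tubule genes, Slc27a2 (-0.93), and 5 over the list alone (camera adjusted p = 0.00183; adjusted p = 0.542 with an estimated correlation). So did 3 of 8 organic ion transport genes, with the organic anion transporter gene Slc22a6 (-1.74), and 4 over the list alone, where 1 lay above (camera adjusted p = 0.0121; adjusted p = 0.494 with an estimated correlation). Androgen-responsive genes lay below it for 6 of 11, with Cyp2j13, Cyp7b1 and Cyp2d9 (-1.81), and 9 over the list alone (median -1.61, camera adjusted p = 5.42e-06; adjusted p = 0.494 with an estimated correlation). Oxidative phosphorylation and fatty acid oxidation genes shifted below with 0 of 11 and 1 of 9 called and 0 and 3 over the list alone, where 1 fatty acid oxidation gene lay above (camera adjusted p = 0.00299 and 0.0207; adjusted p = 0.494 with an estimated correlation for each). Without P0 the calls of the fatty acid oxidation and ketogenesis, organic ion and drug transport, oxidative phosphorylation and Wnt pathway lists ended (camera adjusted p = 0.0974, 0.0691, 0.142 and 0.0957). Without P90 that of the thin limb and inner medulla list ended (0.374). The call of the collecting duct principal cell list ended without P0, P20 or P90 (0.126, 0.0729 and 0.248), and that of the developing stroma list without P0, P2, P4, P6, P8, P10 or P30 (0.0504 to 0.382). Under a stricter filter the developing stroma (0.220) and Wnt pathway calls ended. Test and median or mean differed in sign for the distal convoluted and connecting tubule, hepatocyte, Hedgehog, fetal growth and immediate early lists, none of which was called.

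In all 152 genes departed in cortex (limma), 87 above and 65 below the line, and 654 in medulla, 377 above and 277 below; 1618 and 2473 passed at unadjusted p under 0.05. In cortex the balance depended on the scaling and filter, with 77 above and 88 below after cyclic loess and 82 and 39 under a stricter filter. Both counts depended on single ages. In cortex they were 433, 60, 18, 12, 14, 553 and 1413 without P0, P4, P6, P8, P10, P30 and P90. In medulla they were 10, 285, 166, 156, 111, 1404 and 2197 without P0, P4, P6, P8, P10, P30 and P90, and no medulla gene named here was called without P0. Without P4, P6 and P10 together 1 gene was called in each region.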

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

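The splits of the samples were planned, apart from those that permute residuals; these and the tests of the androgen-responsive genes, the proximal tubule genes and Ucp1 were chosen after the result was seen. The tests of the random list, liver RNA, scaling and whole cortex were also rewritten after their first values were known: the random list test now allows for the choice of step, the liver test has 1 more condition, the scaling label was changed to open, and a sign test was dropped. The residual splits and the permutation of ages for Ucp1 were added after the first counts and p-values were known, and the label of the relation with Cidea was then changed to open.

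A value far from the others was looked for in 97 sets of 9 values, 1 per age. The sets were medulla minus cortex differences of named genes, array measures, and levels of neighbouring tissue markers. Such a value was found in 5 sets, and chance gives about 1 set in 20. All 5 were array measures or tissue markers and none was a regional difference, so the rate over all sets does not describe each kind. The P20 medulla array had a highest correlation with any other medulla array of 0.961, where the next lowest was 0.985. The fat genes Adipoq and Cidea read 9.02 and 9.11 on the P4 medulla array, where the next medulla arrays read 8.46 and 8.32. The liver genes Apoa1 and Ahsg read 9.44 and 9.12 on the P2 medulla array, where the next medulla arrays read 8.78 and 8.30.

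Trends that differed between the regions by the interaction test came to 36 genes. Medulla slope minus cortex slope was 1.67 for Reln, 1.58 for Hs6st2, 1.57 for Gstm2, 1.45 for Sox9, 1.38 for Hoxb6 and 0.94 for Sall1, and -3.12 for Nts, -1.92 for Ranbp3l, -1.80 for Gas6, -1.79 for Gsta3 and -1.75 for Hao2. The list medians that differed by camera at the preset correlation were 1.32 for ureteric tip, 0.52 for cell cycle and 0.50 for committing nephron, and -1.01 for proximal tubule, -0.95 for smooth muscle, -0.53 for extracellular matrix and -0.34 for Wnt pathway; with an estimated correlation 0 of these 7 lists were called (camera adjusted p = 0.608 for each).

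Other splits of the same arrays were counted for each comparison. For the region difference, 1 of 100 splits that swap the regions within ages, the real one, gave as many as 2155 genes. The highest other gave 1078, which argues against chance at the resolution of 100 splits. With ages permuted, 1 of 100, the real one, gave as many for the cortex trend (4945, highest other 3767) and the medulla trend (3514, highest other 3127). The same held for the difference in age trend (36, highest other 2). This argues against chance for each, but for the 2 trends other orders of the ages also called many genes. For the mid-age departures 5 of 100 splits gave as many genes as the real order in cortex (152, highest other 3060) and 5 of 100 in medulla (654, highest other 3707), so chance cannot be excluded by these. The highest of those splits called several times the real count. The reason was not tested, and permuting ages moves the age trend as well as the departure. With the trend left in place and its residuals permuted, 2 of 100 gave as many in cortex (highest other 366) and 1 of 100, the real one, in medulla (highest other 209). As the planned and the added splits differ, whether chance can be excluded for the departures stays open.

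Androgen-responsive genes stepped up from P20 to P30, by a median of 1.27 log2 in cortex and 2.49 in medulla. A random list of unrelated genes is argued against. In each region the step of the androgen-responsive list lay at percentile 100 of the largest of 8 steps in 10000 random lists matched on level. Genes of the random lists were drawn independently, so lists of genes that vary together were not tested, and 35 lists were open to choice. Liver RNA at P30 and P90 is argued against by the medians of the hepatocyte genes. The larger of the median steps of 8 hepatocyte genes was 0.0472 (0.0825 over the 6 above the level filter on any array). However, Apoc3 went from 8.58 to 9.80 in medulla and from 8.22 to 8.72 in cortex. Alb read no higher than 8.31 at P30 and P90, below the filter, but this could not decide. It passed the filter on no array and read 7.91 on the P2 medulla array, where Apoa1 and Ahsg read 9.44 and 9.12. Array handling that differed between P20 and P30 cannot be told apart from age, because there is 1 array per age and region. A candidate explanation is sexual maturation of the males between these ages, which the design does not test apart from age.

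Proximal tubule genes were higher in medulla than in cortex at P0 and P2 and lower from P6. Scaling of the arrays cannot be told apart, since the authors' normalization sets the median difference of all genes, medulla minus cortex, near 0 (-0.00238 at the one of these ages where it lay farther from 0). Whole cortex carried into the medulla samples would bring these genes up to the cortex level at most, but 19 of 20 were higher in medulla at both ages. The hepatocyte list also lay toward medulla at P2 (median gap 0.93, against 0.03 at P0), so the P2 medulla array stood apart in other genes too. Inner cortex with the earliest nephrons in the medulla samples cannot be told apart from expression in the medulla itself. Podocyte genes had a median gap of -0.10 at P0, -0.22 at P2 and -0.76 at P4, but the most mature glomeruli were not measured on their own. Proximal tubule genes were not the only ones to change sides. Fatty acid oxidation genes had gaps of 0.37 at P0 and -0.41 at P10, and distal convoluted and connecting tubule genes 0.15 and -0.90. Thick ascending limb genes stayed higher in medulla (0.39 and 0.21). At P0 ureteric tip (-1.07), nephron progenitor (-0.62) and cell cycle (-0.57) genes were higher in cortex. Whether this bore on the proximal tubule gap was not tested. A candidate explanation is that the oldest, deepest nephrons lay close to the dissection line at birth, and age and region as such also stay open.

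Ucp1 read above the level filter on 15 of 18 arrays and above 9 on 9 of them, up to 11.89 on the P4 medulla array. Its level went with that of Cidea over the 18 arrays, with ages permuted and both regions of an age, which are not independent, moved together (Pearson r 0.844, permutation p = 0.000170, adjusted p = 0.000340; Spearman rho 0.775, permutation p = 0.00112, adjusted p = 0.00224), and r was 0.783 without the P4 medulla and P10 cortex arrays. Cidea was above the level filter on 5 of 18 arrays, and on 3 of the 16 left without those arrays, so most of its values are background readings and a chance correlation stays open. Fat tissue carried with the kidney could bring both, but whether it did cannot be told: with Adipoq r was 0.633 (permutation p = 0.0113, adjusted p = 0.0113; rho 0.567, permutation p = 0.0200, adjusted p = 0.0200) and 0.417 without the same arrays, so that this relation rests on them. Fabp4 and Plin1 read no higher than 8.26 and 8.15 on any array, below the level filter, 3 of 8 adipocyte genes passed it on any array, the 2 relations in this family were adjusted together, and no biological explanation was tested.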

How the results depend on the processing

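The alternatives named as added were chosen after seeing the data; all other alternatives were planned. Direction and side of the threshold were compared for 208 gene results in 4470 comparisons: 3968 were the same, 467 weaker, 14 stronger and 21 reversed, and 62 results were the same in every alternative run for them. For the counts, an alternative counts as the same within 1.5 times; the cause of the differences below was not tested, apart from alternatives that use fewer arrays or ages.

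Region difference counts (2155) were 690 without age as a block, 1002 over P20 to P90, 424 without P4, P6 and P10 (83.0% higher in medulla), and 1464 to 2236 with each age left out. Cortex trend counts (4945) were 7489 over all 13920 probes, where more items were tested, 2952 over P0 to P10, and 4195 to 4949 with each age left out. Medulla trend counts (3514) were 353 over P0 to P10 and 1337 to 4140 with each age left out. Difference in age trend counts (36) were 1 on untransformed days, 395 on rank of age, 6 without age as a block, 1511 over P0 to P10, 0 in limma without P4, P6 and P10 (1439 at unadjusted p under 0.05), and 0 to 169 with each age left out (1257 and 1492 at unadjusted p under 0.05 without P2 and P30, which gave 0). Cortex departure counts (152) were 783 with array weights, 1 without P4, P6 and P10, and 12 to 1413 with each age left out. Medulla departure counts (654) were 3756 with array weights, 428 with no filter, 1 without P4, P6 and P10, and 10 to 2197 with each age left out. List calls (70) were 2 with an estimated correlation and 64 to 74 with each age left out; 14 of the 70 ended without P0 and 16 without P90, and 13 of the 66 that could be run ended under the strict filter, which leaves fewer members.

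Over P0 to P10 alone, which uses fewer ages, 17 medulla trends changed sign. None of them was called there (adjusted p in limma from 0.0595 to 0.993). As slopes extended to P90 they were: Apcdd1 0.49, Cdkn1c 0.97, Col4a1 0.0576, Cox5a -0.0717, Cyp2e1 -1.45, Cyp4a12a -0.0556, Cyp4b1-ps2 -0.0545, Eri2 -0.00570, Fstl1 0.36, Inmt -0.84, Ndn 0.0914, Ndufv1 -0.15, Nfat5 1.02, Nrep 0.91, Slc22a12 -0.23, Slc47a1 -0.87 and Wnt5a 0.36. In cortex Inmt reversed with a call (-1.01, adjusted p = 0.0329 in limma), and Cyp4a12a changed sign without one (-0.18). Over P20 to P90 alone the region differences of Apcdd1 (-0.0262) and Sox9 (0.000782) changed sign without a call. No list reversed in the settings run for lists, which were the estimated correlation, each age left out, the added normalizations, the strict filter, and the fit without P4, P6 and P10. Under the 3 added normalizations (quantile, cyclic loess, common median), 204, 205 and 207 of 208 gene results were the same. Without P4, P6 and P10, 131 of 208 were the same and 77 weaker. On untransformed days 80 of 103 were the same and 23 weaker.

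Not run were the alternatives that start from scanner signals (background correction with another offset, scaling or cyclic loess after it), the detection p filter and the chip as a block, since no header ties those columns to samples and no chip is given; the deposited values, planned as an alternative, are the ones used throughout. Signal over background limits dim genes, whose differences are compressed.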

Other observations

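Gaps between the regions were also read by age for lists whose difference in age trend was not called. A change of these gaps with age was therefore not shown. Urothelium genes were higher in medulla by a median of 0.95 at P0 and 0.51 at P90, and thin limb and inner medulla genes by 1.21 and 0.34. Thick ascending limb genes had a gap of 0.39 at P0, 0.21 at P10 and 0.82 at P20. Oxidative phosphorylation genes were level at P0 (0.14) and P90 (0.02) and lay at -0.49 at P6 and P10, and glycolysis genes had their widest gap at P4 (0.42). Serpina6, which encodes corticosteroid-binding globulin, read 11.82 in medulla and 8.86 in cortex at P0, 13.31 and 9.52 at P20, and 7.61 and 7.42 at P90. Slc14a2 in medulla read 10.29 at P0, 12.26 at P20 and 10.80 at P90, and stayed at or below 8.64 in cortex.

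Macrophage genes rose with age in the cortex for 4 of 8 (camera adjusted p = 0.0823) and in limma for 0 of 8 in the medulla (camera adjusted p = 0.497). Renin-angiotensin genes had 1 of 4 higher and 1 lower in medulla (camera adjusted p = 0.846), prostaglandin genes 2 of 5 higher (camera adjusted p = 0.134) and immediate early genes 2 of 8 higher (camera adjusted p = 0.121). Erythroid, hepatocyte and adipocyte genes had 0 of 4, 0 of 5 and 0 of 3 called between the regions in limma (camera adjusted p = 0.674, 0.332 and 0.828). These values are given without an explanation.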
